A study of Mus musculus with 8 samples.

How the data were processed

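RNA was sequenced from mouse colon in 2 models of adenoma formation, with 3 adenomas and 1 section of non-adenoma colon from each model. Per the labels' protocols, colons were kept in RNAlater, single adenomas and a neighbouring piece of non-tumour colon were taken out, RNA was isolated with Trizol, and 8 single-read libraries were made with an Illumina TruSeq RNA kit. The labels do not say which mouse gave each non-adenoma section, nor that each adenoma of a group came from its own mouse, so the p-values measure the spread between these samples. Whether the counting used strand is not given in the sources used here, so antisense and overlapping genes cannot be told apart.

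The authors deposited a table of estimated counts per gene, a table of FPKM values and a table of ratios, per the file headers. The genome build was mm9, per the submitters' processing notes, and no coordinates are printed because the reference at hand is a later build. The aligner, the counting tool and the annotation are not given in the sources used here. In all 8 libraries the lowest estimated count the authors deposited was exactly 1. Over 657 genes, the deposited FPKM per count had a log2 SD between libraries of 0.236, and of 0.0671 once 1 was subtracted from both values. The deposited estimated counts were therefore read as counts with 1 added, 1 was subtracted, and the values were rounded to whole numbers. The authors' deposited ratio, the fold of each adenoma over the non-adenoma library of its model, equalled the ratio of the deposited FPKM values within 0.01 for 99.3% of values. The tables hold 31189 genes, of which 27 carry dates in place of symbols.

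Library totals ranged from 18156741 to 22719895 counts. A count of 0 allows up to 3 counts, or 0.128 to 0.172 CPM (counts scaled to library size) depending on the library. Such limits and the counting intervals of single ratios cover counting error only.

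Differences were tested with edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) after TMM scaling and edgeR's filter by expression over the 4 groups (minimum count 10, minimum total 15), which left 17218 genes. P-values were adjusted by the Benjamini-Hochberg method within each comparison, and a gene was called at an adjusted p under 0.05. All adjusted p-values given without another tool's name come from this test, or for gene lists from camera in limma 3.58.1. Standard errors (SE) are the absolute log2 fold change divided by the square root of the F statistic. CPM values use TMM-scaled library sizes and are given as mean ± SD (n = 3) for adenomas and as single values for the non-adenoma sections. The fit with a mean for each of the 4 groups used all 8 libraries and left 4 residual degrees of freedom. The change shared by both models was fitted with terms for model and tissue, with 5 residual degrees of freedom. Each lone non-adenoma library was assumed to vary like the adenomas, since no spread between non-adenoma sections can be measured here.

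The 5 comparisons, the rule for named genes, 30 gene lists and most alternatives were fixed before the data were examined. Named genes were the 8 highest and 8 lowest log2 fold changes among called genes with a mean log2 CPM of at least 2 and no overlap between the groups' libraries, leaving out unnamed gene models. The rule adds up to 4 members of each list with the smallest p, and Apc, Ctnnb1, Axin2, Lgr5, Myc and the sex-linked genes whatever their values. The text names part of the genes under this rule, and that part was chosen after the values were seen. The alternatives were run gene by gene on such a part only, called the followed genes below. Of 444 genes on the lists 437 were tested. The lists cover WNT targets, stem cells, fetal and regenerative genes, colonocytes, goblet, enteroendocrine, Paneth and tuft cells, proliferation, ribosome biogenesis, splice regulators, inflammation, neutrophils, interferon and antigen presentation, macrophages, T cells, B and plasma cells, mast cells, smooth muscle, enteric nerve (neurons, glia and interstitial cells of Cajal), fibroblasts and matrix, matrix proteases, endothelium, adipocytes, epithelium, posterior Hox genes, immediate early and stress genes, and blood. These 28 lists were tested with camera at a preset correlation of 0.01 and again with an estimated correlation. The sex-linked genes and the driver genes Apc and Ctnnb1 were given as values. Where a whole group had no count, a fold is a lower bound against 3 counts per library.

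The gene-by-gene test of each comparison was run on simulated counts, with 50 genes changed at each of 2-, 4-, 8- and 16-fold. All libraries, the sections included, were drawn with the same spread per gene. Few genes were changed in the simulation, while the real fit of the shared change called 34.1% of genes, and the Benjamini-Hochberg cutoff depends on that share. The shares recovered therefore hold only if sections vary like adenomas and as few genes change. List tests and overlaps were not simulated. edgeR recovered 6%, 50%, 74% and 94% of the changed genes for ApcMin/+ adenoma against non-adenoma, and 2%, 52%, 84% and 96% for AOM/DSS adenoma against non-adenoma. For AOM/DSS against ApcMin/+ adenomas it recovered 20%, 80%, 88% and 86%, and for the change shared by both models 24%, 84%, 96% and 94%. For the difference of the adenoma effect between models it recovered 0%, 10%, 56% and 68%.

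The alternatives were DESeq2 size factors and upper quartile scaling in edgeR, the DESeq2 1.42.0 Wald test, no filter, a filter of 10 counts in 3 libraries, a robust spread, and an absolute log2 fold change of at least 1. Further ones were limma on log2(FPKM + 1) and log2(FPKM + 0.1) at a mean FPKM of at least 1, limma on log2(FPKM + 1) without that filter, each adenoma library left out, the libraries of a comparison alone, and the replicate number as a block. Each section was left out only in gene-by-gene fits of the shared change, and list tests left out adenoma libraries only. Keeping the added 1 was chosen after seeing the data, as was leaving out gene copies, their parents, ribosomal proteins, unnamed gene models, pseudogenes and immune receptor segments. Replicate pairs differed by more than sampling noise (chi-square per gene of 26.0 to 92.7), so each library was counted as 1 sample.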

Results

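Gene expression was compared in 2 kinds of mouse colon adenoma with active canonical WNT signalling, each set against non-adenoma colon of its own model. ApcMin/+ mice carry a mutant allele of Apc, a negative regulator of the WNT pathway, and were killed at 110 to 120 days of age. In the other model, wild-type C57BL/6J mice received the carcinogen azoxymethane (AOM, 10 mg/kg) at 6 to 7 weeks of age and 3 cycles of 2% dextran sulfate sodium (DSS), which injures the colon lining, and were killed 70 days after AOM. Per the labels, the AOM/DSS adenomas expressed a β-catenin that resists degradation and were wild type for Apc. Each model gave 3 adenomas and 1 non-adenoma section. The ApcMin/+ section had 20674848 counts and its adenomas 20775903, 22719895 and 21784486. The AOM/DSS section had 20769274 counts and its adenomas 21926558, 18156741 and 22097184.

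The first principal component held 42.9% of the variance and placed the non-adenoma sections at -141 (ApcMin/+) and -90.7 (AOM/DSS) and the adenomas between -16.4 and 64.8. The second held 32.7% and placed the ApcMin/+ libraries between -85.6 and -17.1 and the AOM/DSS libraries between 44.3 and 88.7. ApcMin/+ adenoma 3 lay nearest to the non-adenoma sections on the first component. Against the ApcMin/+ section its median log2 difference was -1.67 over colonocyte genes and -1.52 over smooth muscle genes, where adenoma 1 had -3.94 and -3.15 and adenoma 2 had -4.12 and -3.04. Y-linked genes had counts in all 8 libraries, with sums over Ddx3y, Uty, Kdm5d and Eif2s3y of 247 to 397 CPM. Apc stood at 132 CPM in the ApcMin/+ section and 152 ± 2.02 CPM (SD, n = 3) in its adenomas, and at 98.8 and 124 ± 24.6 CPM in the AOM/DSS section and adenomas. Neither difference passed edgeR's test (adjusted p = 0.53 and 0.356), and the counts do not separate a mutant from a normal allele.

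The first comparison asked what differs between ApcMin/+ adenomas and non-adenoma colon. WNT target genes rose. Axin2, a feedback inhibitor of the pathway, went from 21.4 to 302 ± 71.9 CPM (SD, n = 3), a log2 fold change of 3.82 ± 0.43 (SE, adjusted p = 0.0108). The WNT transcription factors Lef1 and Tcf7 rose by 4.25 ± 0.39 and 3.65 ± 0.33 on the log2 scale, the inhibitors Nkd1 and Apcdd1 by 4.83 ± 0.41 and 6.81 ± 0.41, and Rnf43, a ligase that removes WNT receptors, by 3.06 ± 0.37. Of 26 WNT targets 20 rose and 0 fell (23 and 0 adjusted over the list alone), with a median of 3.08, or 3.10 with a gene at the limit of detection left out. The list passed with the preset correlation (adjusted p = 2.88e-29) and had an adjusted p = 0.128 with an estimated correlation. Myc rose by 1.00 ± 0.18 (adjusted p = 0.0224) and Ctnnb1, which encodes β-catenin, by 0.99 ± 0.25 (adjusted p = 0.0441). The stem cell marker Lgr5 went from 14.7 to 94.7 ± 33.9 CPM and did not pass (2.68 ± 1.15, adjusted p = 0.138). In the stem cell list 3 of 13 rose (7 higher and 1 lower adjusted over the list alone), including Ascl2 (2.37 ± 0.51), with a median of 1.18. That list had an adjusted p of 0.0028, or adjusted p = 0.389 with an estimated correlation.

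Paneth cell genes, known from the crypts of the small intestine, rose in 8 of 10 cases (9 adjusted over the list alone), with a median of 5.66, or 5.46 with genes at 0 set to their bound. Mmp7, which encodes matrilysin, went from 3.67 to 455 ± 184 CPM, and the lysozyme gene Lyz1 from 39.0 to 1693 ± 868 CPM. Defa24 rose by 5.47 ± 0.70, though defensin genes are near copies of each other and their counts are uncertain. Of 24 proliferation genes 23 rose (24 adjusted over the list alone, median 1.67), including the replication genes Mcm5 (1.61 ± 0.23) and Rrm2 (2.39 ± 0.36). Ribosome biogenesis genes rose in 8 of 20 cases (16 higher and 1 lower adjusted over the list alone, median 0.71), including Nop56 (1.44 ± 0.28) and Mybbp1a (1.27 ± 0.18). Splice regulators rose in 5 of 19 cases (10 higher and 1 lower adjusted over the list alone, median 0.63), including Srsf1 (0.80 ± 0.21) and Hnrnpa1 (1.42 ± 0.37). These lists had adjusted p of 4.99e-15, 1.61e-17, 3.59e-05 and 0.0061 in that order. With an estimated correlation it was adjusted p = 0.128, 0.389, 0.389 and 0.524.

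Part of the protease and inflammatory genes rose as well. Of 14 matrix protease genes 9 rose (11 adjusted over the list alone, median 2.14), led by the stromelysin Mmp10 (6.57 ± 0.67) and the collagenase Mmp13 (5.46 ± 0.69). Of 18 fetal and regenerative genes 6 rose (8 adjusted over the list alone, median 1.22), including the cytokine gene Il11 (6.09 ± 0.77). Of 23 inflammation genes 7 rose (8 adjusted over the list alone, median 2.29, or 1.94 with bounds), including Saa3 (5.68 ± 0.47) and Ptgs2, which encodes cyclooxygenase 2 (3.31 ± 0.53). Of 14 neutrophil genes 4 rose (9 adjusted over the list alone, median 2.34), including S100a8 (2.81 ± 0.73) and S100a9 (3.05 ± 0.76). Of 11 mast cell genes 3 rose (6 adjusted over the list alone, median 3.44, or 3.40 with 1 gene left out), including Cpa3 (1.57 ± 0.39) and Ms4a2, which had 3 counts in the section and stood 36.0-fold higher (95% counting interval 12.3 to 174). Of 14 immediate early genes 3 rose (5 adjusted over the list alone, median 0.84), including Jun (1.95 ± 0.29) and Egr1 (3.11 ± 0.56). With the preset correlation these lists had adjusted p of 1.17e-08, 1.71e-05, 2.11e-05, 0.000317, 0.000589 and 0.00675 in that order. With an estimated correlation it was adjusted p = 0.128, 0.181 and then 0.389 for each of the other 4.

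Lists of differentiated epithelium, muscle, nerve and fat had medians below 0. In the colonocyte list 6 of 23 fell and 1 rose (14 and 1 adjusted over the list alone), with a median of -2.74. The water channel gene Aqp8 went from 568 to 10.2 ± 11.5 CPM, and Cyp2c55 fell by 5.57 on the log2 scale. Slc9a3, an apical sodium exchanger gene on the same list, rose by 2.16 ± 0.32. Of 16 enteroendocrine genes 5 fell (10 lower and 1 higher adjusted over the list alone, median -2.76, or -2.82 with 1 gene left out), including the hormone gene Gcg (-5.19 ± 1.32). Of 17 goblet cell genes 1 rose and 1 fell (0 and 0 adjusted over the list alone, median -2.74). Of 16 smooth muscle genes 8 fell (11 adjusted over the list alone, median -2.33), including Acta2 (-2.04 ± 0.44) and Mylk (-1.70 ± 0.35). Of 17 enteric nerve genes 2 fell (2 adjusted over the list alone, median -2.64), including Kit (-2.30 ± 0.47). Of 9 adipocyte genes 5 fell (9 adjusted over the list alone, median -4.59, or -4.43 with bounds), including the adipokine gene Adipoq, from 9.52 to 0.0148 ± 0.0256 CPM. Adjusted p with the preset correlation was 5.58e-07, 0.000131, 4.04e-05, 2.02e-07, 2.54e-05 and 1.58e-10 for these lists in order. With an estimated correlation it was adjusted p = 0.389 for the first 5 and adjusted p = 0.0638 for adipocytes. Without ApcMin/+ adenoma 3 Aqp8, Cyp2c55 and Gcg stood at log2 -7.16, -7.57 and -7.58, against -5.79, -5.57 and -5.19 with all libraries. Adipoq had no count in ApcMin/+ adenomas 1 and 3. The general epithelial list had 1 gene higher and 1 lower, Cdx1 (-1.86 ± 0.46), with 1 higher and 7 lower adjusted over the list alone and a median of -0.60. Its adjusted p was 0.0374, or adjusted p = 0.524 with an estimated correlation, and it lost its call without ApcMin/+ adenoma 1 (0.0633) or without AOM/DSS adenoma 1, 2 or 3 (0.0544, 0.08 and 0.087).

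Among called genes named under the rule, the highest fitted fold changes were those of Otop1, a proton channel gene, and Psapl1. Both had 0 counts in the section, with 54.0 ± 15.2 and 28.1 ± 4.88 CPM in adenomas. They were at least 314-fold and at least 164-fold higher, and these bounds alone do not rank them above Irx4. The homeobox gene Irx4 had 2 counts in the section and stood 390-fold higher (95% counting interval 108 to 3221). Onecut2 and Adcy8 rose by 8.14 ± 1.13 and 8.07 ± 0.81. The genes picked as the 8 lowest included Mptx1 (-6.68 ± 1.42) and the selenium-binding protein gene Selenbp1 (-4.09 ± 0.85). Adipoq and Cfd, which entered through the lists, lay lower, at -8.83 and -10.6. The immunoglobulin segments Iglc2 (-4.21 ± 1.10) and Igkv5-39 (-5.07 ± 1.24) fell as well, with counts uncertain between near copies. Without ApcMin/+ adenoma 3 Selenbp1 stood at -5.38, and without adenoma 1 Mptx1, Iglc2 and Igkv5-39 (-7.94, -4.94 and -6.37) did not pass (adjusted p = 0.0646, 0.0869 and 0.0636). In the B and plasma cell list 0 of 14 genes were called over all genes and 10 fell adjusted over the list alone (median -3.56), with an adjusted p of 1.75e-05, or adjusted p = 0.389 with an estimated correlation. The tuft, interferon, macrophage, T cell, fibroblast, endothelial, posterior Hox and blood lists did not pass, with medians of -0.93, -0.63, 0.03, -0.35, -0.12, 0.17, 0.75 and -0.13. Adjusted over the list alone they had 1, 1, 0, 0, 3, 1, 3 and 0 genes higher and 1, 0, 0, 0, 3, 0, 1 and 0 lower. The macrophage list had a mean of -0.09 against its positive median and test. Without AOM/DSS adenoma 2 the interferon list passed as lower (0.0138), and without ApcMin/+ adenoma 1 the posterior Hox list passed as higher (0.0195).

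In all, 2824 of 17218 genes were called, 1731 higher (61.3%) and 1093 lower, and limma on FPKM gave 81.5% or 86.1% higher, or 69.0% without its filter. The share was 53.4% with DESeq2 size factors, 55.9% with upper quartile scaling, 78.5% from the 4 ApcMin/+ libraries alone and 49.3% to 90.1% with 1 library left out. DESeq2 called 4440, and edgeR called 398, 354 and 4419 without ApcMin/+ adenomas 1, 2 and 3, 1581 and 1545 without AOM/DSS adenomas 1 and 3, and 951 from the 4 ApcMin/+ libraries alone. Of 65 followed genes that were called, a part chosen after the values were seen, 27 held under every alternative run on them. They include Axin2, Lef1, Tcf7, Nkd1, Apcdd1, Rnf43, Mmp7, Lyz1 and Mcm5. Of the 65, 33 lost their call without adenoma 1 and 35 without adenoma 2.

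**Figure D1:**
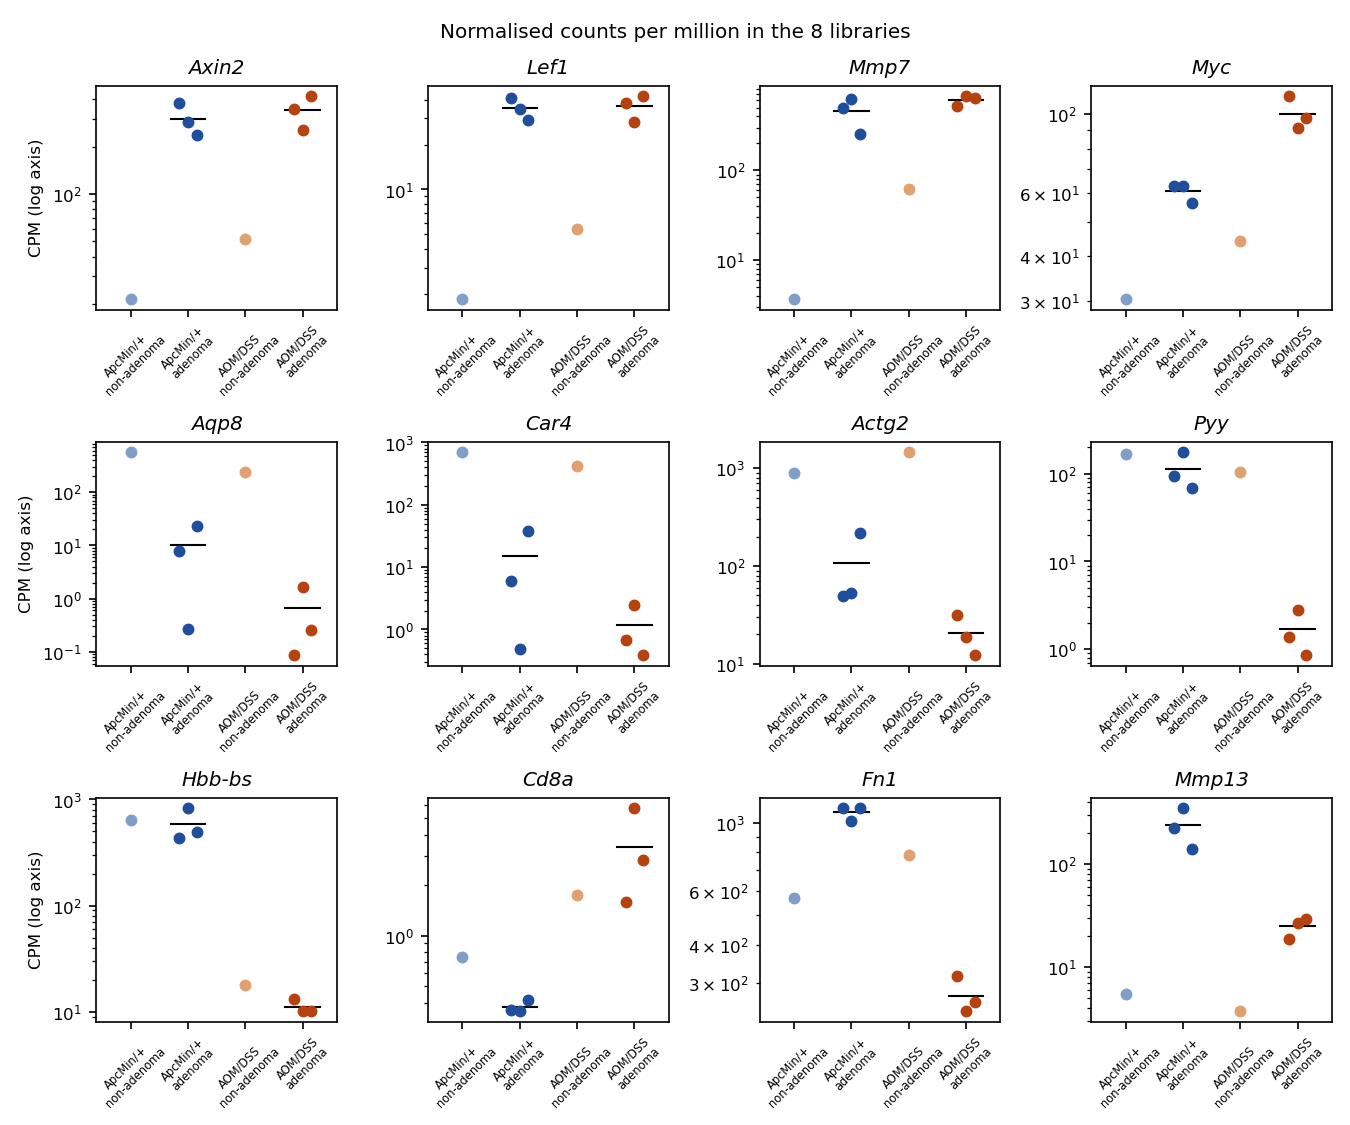
Normalised CPM (log axis) of 12 genes in the 8 libraries, 1 point per library, with a line at the mean of each group of 3 adenomas. Axin2 stands at 21.4 and 52.1 CPM in the non-adenoma sections and at means of 302 and 342 CPM in the adenomas, and Hbb-bs at means of 584 CPM in ApcMin/+ adenomas and 11.1 CPM in AOM/DSS adenomas.

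The second comparison asked the same of AOM/DSS adenomas. WNT targets rose here too, in 16 of 26 cases with 0 lower (21 and 0 adjusted over the list alone) and a median of 2.56. Axin2 went from 52.1 to 342 ± 81.4 CPM (SD, n = 3), a log2 fold change of 2.71 ± 0.40 (SE, adjusted p = 0.0307). Lef1, Tcf7, Nkd1, Apcdd1 and Rnf43 rose by 2.73 ± 0.34, 2.57 ± 0.30, 2.54 ± 0.35, 2.60 ± 0.31 and 2.57 ± 0.35, and Myc by 1.18 ± 0.18 (adjusted p = 0.0309). Ctnnb1 did not pass (0.66 ± 0.25, adjusted p = 0.135), nor did Lgr5, at 3.85 CPM in the section and 55.9 ± 54.4 CPM in adenomas (adjusted p = 0.106). Of 10 Paneth cell genes 6 rose (10 adjusted over the list alone, median 3.31), including Mmp7 from 61.8 to 610 ± 77.4 CPM. Of 24 proliferation genes 5 rose (10 adjusted over the list alone, median 0.66), including Mcm2 (1.28 ± 0.26) and Mcm4 (1.24 ± 0.21). The WNT, Paneth and proliferation lists had adjusted p of 5.05e-21, 4.08e-11 and 3.28e-06, or adjusted p = 0.244, 0.244 and 0.471 with an estimated correlation.

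Smooth muscle genes fell in 12 of 16 cases (16 adjusted over the list alone, median -4.13). The contractile genes Actg2, Des and Cnn1 fell by 6.13, 6.22 and 6.33 on the log2 scale, Actg2 from 1462 to 20.9 ± 9.90 CPM. Of 16 enteroendocrine genes 8 fell (15 adjusted over the list alone, median -5.59, or -5.15 with bounds), including the peptide hormone genes Pyy, from 103 to 1.68 ± 1.02 CPM, and Insl5, from 82.7 to 0.121 ± 0.174 CPM. Of 23 colonocyte genes 3 fell and 2 rose (15 and 2 adjusted over the list alone, median -3.02). Aqp8 and the carbonic anhydrase gene Car4 fell by 8.61 and 8.48, while Slc9a3 rose by 3.06 ± 0.34. In the goblet cell list 0 of 17 were called over all genes, with 14 lower and 1 higher adjusted over the list alone (median -3.42). Of 17 enteric nerve genes 3 fell (10 adjusted over the list alone, median -3.81, or -2.92 with bounds), including Uchl1 (-3.60 ± 0.61). Adjusted p with the preset correlation was 1.36e-27, 2.82e-14, 8.02e-07, 5.3e-08 and 4.99e-08 for these lists in order. With an estimated correlation it was adjusted p = 0.244, 0.244, 0.456, 0.456 and 0.456. Without AOM/DSS adenoma 2 Aqp8 and Car4 stood lower, at -10.43 and -9.57, and did not pass (adjusted p = 0.0634 and 0.0723). Insl5 did not pass without adenoma 2 (-11.57, adjusted p = 0.0634), where its adenomas held 0.0429 and 0 CPM, or without adenoma 3 (-8.88, adjusted p = 0.103), against -9.50 with all libraries.

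Part of the immune and protease genes rose. Mmp10 (3.85 ± 0.58) was among 2 of 14 matrix protease genes that rose (9 higher and 1 lower adjusted over the list alone, median 1.32). Saa3 (3.41 ± 0.41) was the 1 inflammation gene of 23 that rose (3 adjusted over the list alone, median 1.93). Cx3cr1 (1.90 ± 0.29) rose in the macrophage list (1 of 14, or 9 adjusted over the list alone, median 0.96), and Cpa3 (2.02 ± 0.39) in the mast cell list (1 of 11, or 4 adjusted over the list alone, median 2.02). These lists had adjusted p of 6.44e-05, 0.00147, 0.000303 and 0.000165, or adjusted p = 0.254, 0.511, 0.457 and 0.456 with an estimated correlation. The stem cell, ribosome biogenesis, neutrophil and T cell lists had 1, 2, 0 and 0 genes higher and 0, 1, 0 and 0 lower (5, 16, 8 and 0 higher and 1, 1, 0 and 0 lower adjusted over the list alone) and medians of 1.00, 0.84, 2.16 and 1.40. Their adjusted p was 0.00332, 1.21e-05, 0.00521 and 0.0128, or adjusted p = 0.457, 0.456, 0.518 and 0.591 with an estimated correlation. The T cell list lost its call without AOM/DSS adenoma 2 (0.0652).

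The fibroblast and matrix genes Fn1, which encodes fibronectin, and Lum fell by 1.52 and 4.03, and the posterior Hox gene Hoxa13 fell by 2.23. The fibroblast, epithelial and posterior Hox lists passed as lower, with adjusted p of 0.0429, 0.0185 and 0.0154, or adjusted p = 0.518, 0.518 and 0.454 with an estimated correlation. They had 2, 0 and 1 genes lower and 1, 1 and 0 higher (2, 2 and 3 lower and 1, 1 and 0 higher adjusted over the list alone), with medians of -0.19, -0.58 and 0.13. The Hox list had a mean of -0.24, against its median. Without AOM/DSS adenoma 2 the adjusted p of these lists was 0.119, 0.0824 and 0.0624, and the fibroblast list also lost its call without AOM/DSS adenoma 3 (0.0631) and without ApcMin/+ adenomas 2 and 3 (0.0569 and 0.0693). The fetal, tuft, splice regulator, interferon, B and plasma cell, endothelial, adipocyte, immediate early and blood lists did not pass, with medians of 0.49, 0.19, 0.36, 0.79, 1.35, 0.01, 0, -0.31 and -0.71. With genes at 0 set to their bound or left out, the tuft median was 0.37, the adipocyte median -1.49 and the inflammation median 1.89, and the endothelial mean was -0.12, against its median. Over all genes 2 fetal genes rose and 1 fell, 1 tuft gene rose and 1 fell, and 1 adipocyte gene fell. Adjusted over the list alone the fetal list had 7 genes higher and 2 lower, the tuft list 1 and 1, the adipocyte list 0 and 2, and the others 0 and 0. The fetal list passed as higher without ApcMin/+ adenoma 3 or AOM/DSS adenoma 1 or 3 (0.0455, 0.0158 and 0.0325), the splice regulator list without ApcMin/+ adenoma 3 (0.0455) and the interferon list without AOM/DSS adenoma 3 (0.0498), and the blood list as lower without AOM/DSS adenoma 1 (0.0152). Among called genes named under the rule, the highest folds were Onecut2 (5.21 ± 0.92), Defa22 (4.46 ± 0.66), a defensin with uncertain counts, the haptoglobin gene Hp (4.43 ± 0.79) and Cubn (4.39 ± 0.82).

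In all, 862 genes were called, 409 higher (47.4%) and 453 lower, and limma on FPKM gave 60.9% or 71.5% higher, or 34.3% without its filter. The share was 37.6% with DESeq2 size factors, 38.5% with upper quartile scaling and 18.7% (149 higher and 647 lower) from the 4 AOM/DSS libraries alone, so the direction of the majority depends on the setting. DESeq2 called 2917, while edgeR called 132, 14 and 2055 genes without ApcMin/+ adenomas 1, 2 and 3, and 0 (4737 at an unadjusted p under 0.05), 301 and 18 without AOM/DSS adenomas 1, 2 and 3. Of 47 followed genes that were called 0 held under every alternative run on them, and 0 changed direction.

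The calls of both comparisons, which share no library, overlapped in 334 genes higher in both, against 41.1 for independent lists, and in 229 genes lower in both, against 28.8. Opposite calls were made for 3 genes: Fn1, Pdzrn3 and Rpl3-ps1, of which Pdzrn3 and Rpl3-ps1 were chosen after their values were seen. Of the genes called in ApcMin/+ adenomas 95.3% had the same sign in AOM/DSS adenomas, of those called in AOM/DSS adenomas 97.1% had the same sign in ApcMin/+ adenomas, and of all tested genes 76.1%. Across genes, which are not independent replicates, the log2 fold changes had a correlation of 0.53. The overlap, 563 genes in all, was 54, 9 and 1692 without ApcMin/+ adenomas 1, 2 and 3, and 0, 222 and 12 without AOM/DSS adenomas 1, 2 and 3. All comparisons drew on 1 estimate of the spread from the 8 libraries, and with each model fitted on its own 4 libraries the overlap was 154.

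**Figure D2:**
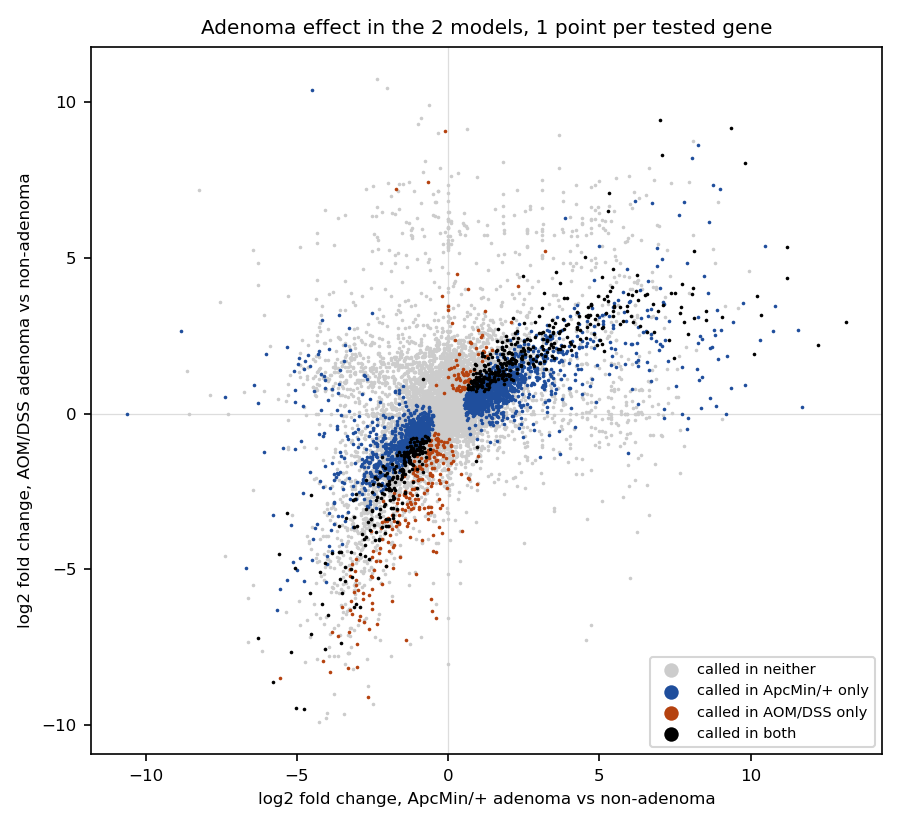
Log2 fold change of adenoma over non-adenoma colon in ApcMin/+ mice (x axis) and AOM/DSS mice (y axis), 1 point per tested gene, coloured by the comparison in which it was called. Genes called in both comparisons lie in the lower left and upper right parts except for 3 genes.

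The change shared by both models was fitted with 2 non-adenoma sections against 6 adenomas. Axin2 rose by 3.21 ± 0.37 (SE, adjusted p = 0.00473), Lgr5 by 3.19 ± 0.84 (adjusted p = 0.0243), Myc by 1.09 ± 0.12 (adjusted p = 0.00473) and Ctnnb1 by 0.82 ± 0.17 (adjusted p = 0.0126). The largest increases among named genes included Mptx2 (6.75 ± 1.11), Onecut2 (6.20 ± 0.89), the complement inhibitor gene Cfi (6.02 ± 1.05) and the transglutaminase gene Tgm4 (5.28 ± 0.81). The largest decreases among named genes included Aqp8 (-7.28 ± 1.21), Car4 (-7.23 ± 1.28), Sycn (-6.72 ± 1.37) and the chloride exchanger gene Slc26a3 (-5.76 ± 1.27). Zg16, a goblet cell lectin gene, went from 6165 CPM to 520 ± 840 CPM in ApcMin/+ and from 4884 CPM to 35.0 ± 29.0 CPM in AOM/DSS mice (SD, n = 3 each). Of 26 WNT targets 23 rose (24 adjusted over the list alone), all 10 Paneth cell genes rose (10 adjusted over the list alone), 13 of 17 goblet cell genes fell and 1 rose (15 and 1 adjusted over the list alone), and 15 of 16 smooth muscle genes fell (15 adjusted over the list alone). These lists had adjusted p of 1.75e-20, 2.6e-09, 9.22e-08 and 1.25e-13, or adjusted p = 0.231, 0.231, 0.291 and 0.291 with an estimated correlation. Medians, means and tests differed in sign for the posterior Hox list (median 0.49, mean 0.39, tested lower), the interferon list (-0.16, 0.00447, tested lower) and the endothelial list (0.01, -0.02, tested higher), none of which passed. Without AOM/DSS adenoma 2 the interferon list and the B and plasma cell list passed as lower (0.0496 and 3.16e-05, against 0.671 and 0.0532 with it). Without the AOM/DSS section Onecut2, Cfi, Tgm4, Axin2 and Aqp8 stood at 8.14, 7.90, 7.74, 3.82 and -5.79, while Car4, Sycn, Slc26a3 and Zg16 (-5.55, -4.74, -4.66 and -3.56) did not pass (adjusted p = 0.0525, 0.0823, 0.0971 and 0.239). Without the ApcMin/+ section Onecut2, Tgm4, Aqp8 and Car4 stood at 5.20, 4.15, -8.60 and -8.48, while Cfi, Lgr5, Slc26a3, Zg16 and Sycn (4.84, 3.85, -6.62, -7.12 and -7.99) did not pass (adjusted p = 0.0614, 0.104, 0.0752, 0.0928 and 0.0519). Without ApcMin/+ adenoma 3 Slc26a3, Zg16, Sycn, Car4 and Aqp8 stood at -7.15, -7.29, -7.42, -8.13 and -7.88. Sycn stood at -7.99 without AOM/DSS adenoma 2.

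In all, 5871 genes were called for the shared change, 3148 higher (53.6%) and 2723 lower, and limma on FPKM gave 73.0% or 74.5% higher, or 66.7% without its filter. The majority was lower with DESeq2 size factors (47.1% higher), upper quartile scaling (48.8%) and an absolute log2 fold change of at least 1 (45.9%), so its direction depends on the setting. Without the ApcMin/+ section 880 genes were called, without the AOM/DSS section 2833, and at an absolute log2 fold change of at least 1 there were 3063. Of 20 followed genes that were called 5 held under every alternative run on them (Onecut2, Tgm4, Aqp8, Axin2 and Myc). Of the 20, 14 lost their call without the ApcMin/+ section and 9 without the AOM/DSS section.

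AOM/DSS adenomas were then compared with ApcMin/+ adenomas. Interferon, T cell and B cell lists were higher in AOM/DSS adenomas with the preset correlation, and had adjusted p = 0.549, 0.549 and 0.583 with an estimated correlation. Of 20 interferon and antigen presentation genes 13 were higher (17 adjusted over the list alone, median 2.22), including the MHC class II genes Cd74, at 200 ± 32.2 CPM in ApcMin/+ and 1150 ± 677 CPM in AOM/DSS adenomas (SD, n = 3 each), and H2-Eb1 (log2 2.51 ± 0.37, SE, adjusted p = 0.00968). Of 16 T cell genes 10 were higher (14 adjusted over the list alone, median 2.47), including Cd3e (2.85 ± 0.55), Cd8a (3.15 ± 0.56) and the regulatory T cell gene Foxp3 (2.72 ± 0.48). Of 14 B and plasma cell genes 8 were higher (13 adjusted over the list alone, median 3.81), including Ms4a1 (4.95 ± 1.12). Against the ApcMin/+ section the median log2 difference of that list was -1.11, 1.95 and -1.33 in AOM/DSS adenomas 1, 2 and 3. It was -0.56 in the AOM/DSS section and -2.72, -4.33 and -3.27 in ApcMin/+ adenomas 1, 2 and 3. By this measure only AOM/DSS adenoma 2 stood above the sections. AOM/DSS adenoma 2 stood apart, with 3.36% of its counts in immunoglobulin genes against 0.717% and 0.389% in the other AOM/DSS adenomas. Without it Ms4a1, Cd8a and Cd74 were higher by 2.92, 2.53 and 1.93 on the log2 scale (adjusted p = 0.0138, 0.0261 and 0.00796), against 4.95, 3.15 and 2.53 with it. Adjusted p with the preset correlation was 4.42e-09, 5.66e-07 and 4.71e-05, and with any 1 adenoma library left out at most 6.69e-06, 3.23e-05 and 0.000663. Mast cell genes were higher in 3 of 11 cases (4 adjusted over the list alone, median 1.60), including the tryptase gene Tpsab1 (5.41 ± 0.50, or 6.10 without ApcMin/+ adenoma 1), and macrophage genes in 4 of 14 (6 adjusted over the list alone, median 0.47), including C1qa (0.88 ± 0.20). Those lists had adjusted p of 0.000471 and 0.0191, or adjusted p = 0.549 and 0.733 with an estimated correlation, and the macrophage list lost its call without AOM/DSS adenoma 2 (0.0889). Tpsab1 differed between the sections as well, at 0.0573 CPM (ApcMin/+) and 10.8 CPM (AOM/DSS), whereas Cd74 stood at 464 and 440 CPM there.

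Part of the matrix, protease and vessel genes were lower in AOM/DSS adenomas. Of 14 matrix protease genes 7 were lower (10 adjusted over the list alone, median -1.04), including Mmp13 (-3.25 ± 0.37). Of 15 fibroblast and matrix genes 7 were lower (9 adjusted over the list alone, median -0.68), including Fn1, at 1081 ± 57.2 CPM in ApcMin/+ and 274 ± 38.6 CPM in AOM/DSS adenomas, and Sparc (-1.29 ± 0.21). Of 18 fetal and regenerative genes 7 were lower and 1 higher (7 and 1 adjusted over the list alone, median -0.43), including Il11 (-2.78 ± 0.37), Ctgf (-2.18 ± 0.19) and Ankrd1 (-3.62 ± 0.51, or -4.30 without AOM/DSS adenoma 3). Of 13 endothelial genes 5 were lower (9 adjusted over the list alone, median -0.69), including Cdh5 (-1.04 ± 0.21) and Emcn (-1.88 ± 0.28). Of 16 smooth muscle genes 5 were lower (7 adjusted over the list alone, median -1.18), including Cald1 (-0.90 ± 0.11). Adjusted p with the preset correlation was 5.66e-07, 5.15e-06, 0.000156, 0.000156 and 0.000154 in that order, and adjusted p = 0.429, 0.549, 0.48, 0.549 and 0.583 with an estimated correlation.

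Inflammation genes went both ways. The nitric oxide synthase gene Nos2 was higher (3.58 ± 0.61, or 4.35 without ApcMin/+ adenoma 1), while Ptgs2 (-2.42 ± 0.31) and Saa3 (-1.78 ± 0.23) were lower, as was Il6, at 2.56 ± 2.35 CPM in ApcMin/+ and 0.0749 ± 0.0469 CPM in AOM/DSS adenomas (log2 -4.97, or -3.87 without ApcMin/+ adenoma 2). Nos2 also differed between the sections, at 3.78 CPM (ApcMin/+) and 110.7 CPM (AOM/DSS), and AOM/DSS adenoma 1 (110.1 CPM) did not exceed its section. In the inflammation list 3 of 23 were higher and 3 lower (5 and 4 adjusted over the list alone), and it did not pass (median -0.38, mean 0.23, adjusted p = 0.6). Of 14 neutrophil genes 2 were lower (5 adjusted over the list alone, median -0.86), including S100a8 (-1.68 ± 0.44). The neutrophil list had an adjusted p of 0.0159, or adjusted p = 0.733 with an estimated correlation, and lost its call without ApcMin/+ adenoma 1 (0.0613) or AOM/DSS adenoma 1 (0.0741).

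WNT targets as a list did not pass between the adenoma types (median 0.05, mean -0.08, adjusted p = 0.591), with 2 of 26 higher and 2 lower (2 and 2 adjusted over the list alone). Sox9 and Myc were higher (0.97 ± 0.26 and 0.72 ± 0.12), Apcdd1 was lower (-2.07 ± 0.19), and Axin2 and Lgr5 did not pass (0.18 ± 0.24, adjusted p = 0.618, and -0.76 ± 0.68, adjusted p = 0.454). Ctnnb1 was lower (-0.63 ± 0.17, adjusted p = 0.0445). Of 10 Paneth cell genes 5 were higher (5 adjusted over the list alone, median 1.03), including the defensin gene Defa3 (2.59 ± 0.34), whose counts are uncertain. Of 16 enteroendocrine genes 3 were lower (6 adjusted over the list alone, median -2.80, or -2.79 with bounds), including Pyy, at 113 ± 55.6 CPM in ApcMin/+ and 1.68 ± 1.02 CPM in AOM/DSS adenomas. Of 17 enteric nerve genes 2 were lower (2 adjusted over the list alone, median -2.01, or -1.38 with bounds). Those lists had adjusted p of 0.00193, 7.04e-05 and 0.00731, or adjusted p = 0.549, 0.549 and 0.733 with an estimated correlation, and the nerve list lost its call without ApcMin/+ adenoma 3 (0.174). The splice regulator genes Srsf5 and Clk1 were higher (0.86 ± 0.12 and 0.79 ± 0.11) in a list that did not pass (3 of 19 higher, 5 higher and 1 lower adjusted over the list alone, adjusted p = 0.715), and Hoxa13 was lower (-2.35 ± 0.15). The colonocyte, goblet, tuft, stem cell, proliferation, ribosome biogenesis, adipocyte, epithelial, posterior Hox and immediate early lists did not pass (adjusted p between 0.0916 and 0.892). Their medians were -0.80, -1.52, 0.23, 0.05, -0.06, -0.06, 0, 0.06, -0.02 and -0.02, and the proliferation list had a mean of 0.000749. The tuft and adipocyte medians were 0.39 and 0.15 with genes at 0 set to their bound or left out. In these lists 1, 0, 2, 1, 0, 0, 0, 0, 0 and 0 genes were higher and 2, 0, 2, 0, 0, 0, 0, 1, 2 and 2 lower (1, 0, 3, 0, 0, 0, 0, 0, 0 and 0 higher and 2, 0, 2, 0, 0, 0, 0, 0, 2 and 2 lower adjusted over the list alone). The colonocyte list passed as lower without ApcMin/+ adenoma 2 (0.00426), the goblet list without ApcMin/+ adenoma 1 or 2 or AOM/DSS adenoma 1 (0.00162, 0.00804 and 0.0422), and the proliferation list without ApcMin/+ adenoma 3 (0.0351).

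All 5 blood genes were lower in AOM/DSS adenomas (5 adjusted over the list alone, median -5.71), with counts that are uncertain between near-identical globin genes. Hbb-bs stood at 584 ± 214 CPM in ApcMin/+ and 11.1 ± 1.70 CPM in AOM/DSS adenomas (SD, n = 3 each), and Alas2, which encodes the erythroid enzyme of haem synthesis, was lower as well (-5.47 ± 0.35). The list had an adjusted p of 2.09e-28, or adjusted p = 0.162 with an estimated correlation. Counts of several genes and their named copies also differed by model in adenomas and sections alike. Copies of Rps2 took 18.9% to 21.5% of the counts of Rps2 and its copies in the ApcMin/+ libraries and 96.5% to 97.5% in the AOM/DSS libraries, with Rps2 lower (-5.05 ± 0.26) and Rps2-ps10 higher (5.81 ± 0.25). Tpm3-rs7 was the highest named gene (9.07 ± 0.24), and its counts are uncertain for the same reason.

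In all, 3122 genes were called between the adenoma types, 1761 higher and 1361 lower in AOM/DSS adenomas, and 1891 at an absolute log2 fold change of at least 1. The count was 1333 and 779 without ApcMin/+ adenomas 1 and 2, and 1827, 2018 and 2026 without AOM/DSS adenomas 1, 2 and 3. Of these, 2627 (84.1%) had the same sign between the non-adenoma sections, against 67.2% of all tested genes, and 868 of them differed there by at least 1 on the log2 scale. Of 56 followed genes that were called 23 held under every alternative run on them. They include Fn1, Mmp13, Il11, Ctgf, Ptgs2, Pyy, Hoxa13, Tpsab1 and Hbb-bs. Of the 56, 25 lost their call without ApcMin/+ adenoma 2.

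**Figure D3:**
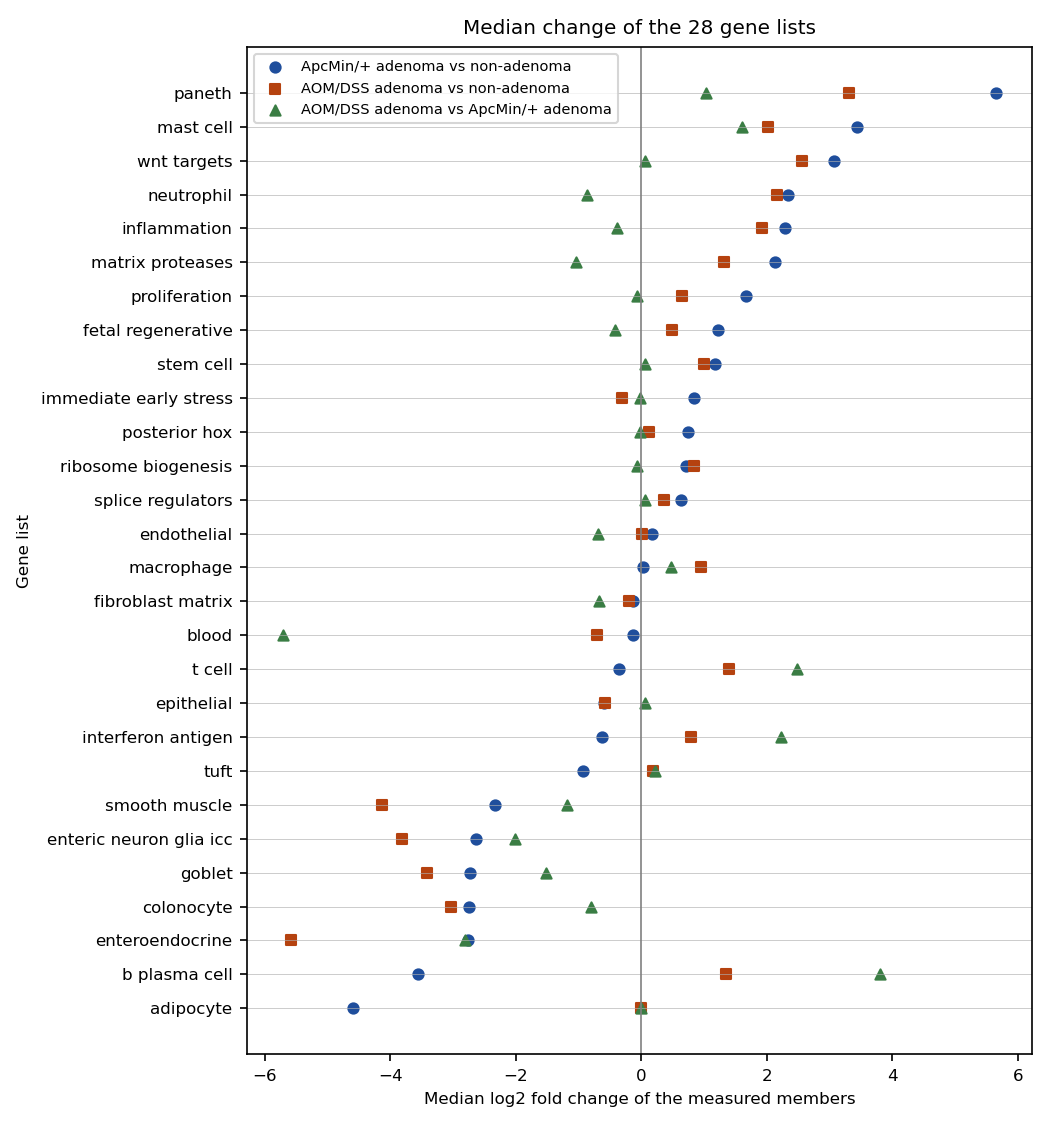
Median log2 fold change (x axis) of the measured members of 28 gene lists (y axis) in 3 comparisons, told apart by colour and symbol. WNT targets have medians of 3.08 and 2.56 in the adenoma against non-adenoma comparisons and 0.05 between adenoma types, and blood genes have -5.71 between adenoma types.

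**Figure D4:**
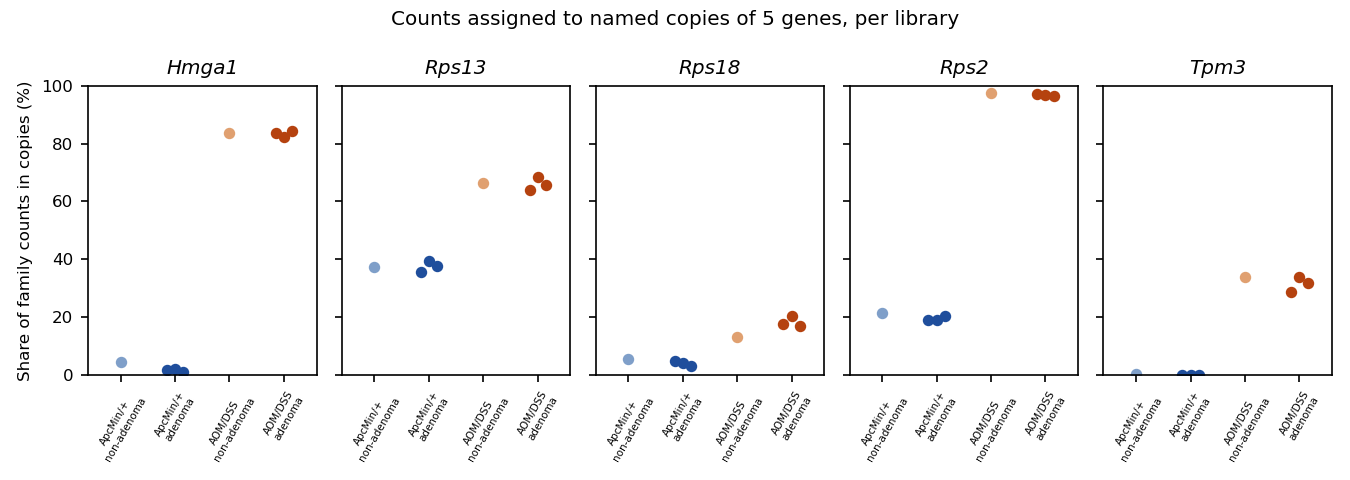
Share of the counts of each of 5 genes and its named copies that was assigned to the copies (y axis, percent) in the 4 groups (x axis), 1 point per library. The genes were chosen after their values were seen, and the Hmga1 share lies between 0.842% and 4.24% in ApcMin/+ libraries and between 82.2% and 84.3% in AOM/DSS libraries.

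The last comparison tested whether the adenoma effect differed between the models, as the AOM/DSS effect minus the ApcMin/+ effect. The log2 differences were -4.20 ± 0.42 for Apcdd1, -2.44 ± 0.29 for Fn1 and -1.11 ± 0.48 for Axin2, and none passed (adjusted p = 0.138, 0.189 and 0.623). For Myc, Ctnnb1, Apc and Lgr5 they were 0.18 ± 0.24, -0.33 ± 0.34, 0.12 ± 0.30 and 1.17 ± 1.44. edgeR called 0 genes, with 1369 at an unadjusted p under 0.05 and a smallest adjusted p of 0.112, while DESeq2 called 191 and limma on FPKM called 1, 4 and 267 in its 3 settings. A gene called in 1 model alone is therefore not shown by edgeR to differ between models.

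The non-adenoma sections are 1 library each and are given as values only. Their median log2 difference (AOM/DSS minus ApcMin/+) was 0.82 over WNT targets, 3.18 over Paneth cell genes, 0.95 over proliferation genes and 1.05 over interferon and antigen presentation genes. Over inflammation, mast cell and immediate early genes the difference was 1.04, 1.04 and 0.81. The median difference was -3.42 over adipocyte genes, -0.91 over colonocyte genes, -5.14 over blood genes and 0.68 over smooth muscle genes. Axin2 stood at 52.1 CPM in the AOM/DSS section and 21.4 CPM in the ApcMin/+ section, and Mmp7 at 61.8 and 3.67 CPM.

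The authors' deposited table of FPKM ratios, in which 1 was part of each FPKM value, gave Axin2 at 31.4, 18.98 and 18.18 in the ApcMin/+ adenomas and at 9.87, 7.23 and 12.51 in the AOM/DSS adenomas. In the authors' deposited table the WNT inhibitor gene Notum, chosen after its values were seen, stood at 171.93, 157.74 and 117.54, and at 10.02, 10.45 and 31.73. The authors' deposited table held 3242, 2846 and 2048 genes with a ratio of at least 2 in the ApcMin/+ adenomas and 1712, 2316 and 2054 in the AOM/DSS adenomas.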

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

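The tests of adenoma tissue and of a repair response in the AOM/DSS section were chosen after the result was seen. The adenoma effect in AOM/DSS mice was set against that in ApcMin/+ mice for the 28 lists, and 15 differed in camera with the preset correlation (adjusted p from 6.33e-12 to 0.0153). None passed with an estimated correlation (smallest adjusted p = 0.204 with an estimated correlation). The median log2 difference (AOM/DSS minus ApcMin/+) was below 0 for WNT targets (-0.90), fetal genes (-0.41), enteroendocrine genes (-2.47), Paneth cell genes (-2.32), proliferation (-0.93), inflammation (-0.37), smooth muscle (-1.68), matrix proteases (-0.90), posterior Hox genes (-1.71) and immediate early genes (-0.77). It was above 0 for interferon and antigen presentation genes (0.93), macrophages (1.06), T cells (2.19), B and plasma cells (4.38) and adipocytes (6.11, or 1.61 with genes at 0 set to their bound or left out). With such bounds the enteroendocrine, inflammation and smooth muscle medians were -2.28, -0.22 and -1.63.

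Adjusted over the list alone, 6 WNT, 4 fetal, 1 enteroendocrine, 6 Paneth, 4 inflammation, 4 protease, 2 Hox and 1 immediate early gene had a lower effect in AOM/DSS mice, 2 interferon genes a higher and 1 a lower one, and 3 adipocyte genes a higher one, while 0 genes were called over all genes by edgeR (1369 at an unadjusted p under 0.05, and 191 by DESeq2). The inflammation list lost its call without AOM/DSS adenoma 1 or 3 (0.139 and 0.0593), and the interferon list without ApcMin/+ adenoma 3 or AOM/DSS adenoma 2 (0.0504 and 0.0509). Further lists passed with 1 library left out: colonocyte (2.18e-05) and splice regulators (0.00712) without ApcMin/+ adenoma 3, goblet (0.0426) and fibroblast (0.0426) without ApcMin/+ adenoma 1, nerve (0.0217) without ApcMin/+ adenoma 2, tuft (0.0404) and fibroblast (0.0357) without AOM/DSS adenoma 1, neutrophil (0.0246) without AOM/DSS adenoma 2 and tuft (0.0388) without AOM/DSS adenoma 3. Median and mean differed in sign for the colonocyte (0.04 and -0.17), ribosome biogenesis (0.03 and -0.04), mast cell (0.01 and -0.53) and fibroblast (0.10 and -0.26) lists.

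Fn1 and Pdzrn3 rose in ApcMin/+ adenomas and fell in AOM/DSS adenomas, with differences of -2.44 and -2.05 on the log2 scale, and Rpl3-ps1 fell in ApcMin/+ and rose in AOM/DSS adenomas (1.96). Each of the 3 adenomas of a model lay on the same side of its section. The differences did not pass edgeR's test (adjusted p = 0.189, 0.244 and 0.216), and Rpl3-ps1 is a copy of a ribosomal protein gene with uncertain counts.

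Part of the lists that rose in adenomas stood higher in the AOM/DSS section than in the ApcMin/+ section, by medians of 0.82 over WNT targets, 3.18 over Paneth cell genes and 0.95 over proliferation genes, which lowers these folds in AOM/DSS mice. Inflammation (1.04), mast cell (1.04) and immediate early genes (0.81) stood higher in the AOM/DSS section as well. Matrix proteases (-0.36) and neutrophil genes (-0.53) stood lower there, so the sections do not account for the lower protease effect (-0.90). Adenoma tissue within the AOM/DSS section may add to this: 41 genes that rose in ApcMin/+ adenomas, under 1 CPM in the ApcMin/+ section and over 16 CPM on average in AOM/DSS adenomas, stood in the AOM/DSS section at a median of 9.55% of the adenoma level (quartiles 6.99% and 13.5%). The log2 SD of that share was 2.10 times the SD between AOM/DSS adenomas, and 2.38, 1.99 and 2.22 times at minimums of 8, 32 and 64 CPM (70, 19 and 13 genes), around a bound of 2. The bound and the minimums were set after values were seen, so adenoma tissue within the section stays open. A repair response to DSS was taken to raise fetal and regenerative genes above WNT targets. The fetal median (-0.02) lay 0.83 below the WNT median (a difference of -0.83), so that condition was not met. Adenoma tissue within the section could raise the WNT median on its own, so this test cannot decide on repair. With 1 section per model, a difference between the models' non-adenoma colon stays open and untested.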

How the results depend on the processing

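Keeping the added 1 and leaving out gene copies were chosen after the results were seen. Of 188 calls of followed genes 55 held under every alternative run on them, and over all alternatives 3045 calls were kept, 595 lost and 0 turned. Of 87 list calls none held with an estimated correlation (smallest adjusted p = 0.0638 with an estimated correlation, for adipocytes in ApcMin/+ mice). Where a call or count moved, the cause was not tested beyond the smaller number of libraries or genes.

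For ApcMin/+ adenoma against non-adenoma, DESeq2 called 4440 genes, the model's own 4 libraries 951, and the fits with 1 library left out 354 to 4419. For AOM/DSS adenoma against non-adenoma it was 2917 with DESeq2, 1361 without gene copies and 0 to 2055 with 1 library left out. Between adenoma types it was 1891 at an absolute log2 fold change of at least 1, 1920 with limma on FPKM without a filter and 779 to 2157 with 1 library left out. For the shared change it was 3063 at an absolute log2 fold change of at least 1 and 880 to 5912 with 1 library left out. For the difference of the effects DESeq2 called 191 and limma on FPKM 1 at log2(FPKM + 1), 4 at log2(FPKM + 0.1) and 267 without a filter, against 0 with edgeR. The overlap was 1920 with DESeq2, 154 with each model's own 4 libraries, 889 without gene copies and 0 to 1692 with 1 library left out. limma on log2(FPKM + 1) moved the median log2 fold change of all genes to 0.30, 0.24 and 0.27 for ApcMin/+, AOM/DSS and the shared change, against 0.03, 0.14 and 0.07.

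With the replicate number as a block 541 genes were called between adenoma types, and 26 of 55 calls of followed genes were lost. The labels do not say that the numbers pair samples. Same-numbered adenomas had deviations from their group mean with correlations of -0.11, -0.32 and -0.28, and none correlated best with its own number. With 3 adenomas per group such deviations are tied to each other, so this check cannot exclude a link between same-numbered samples.

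Values that did not pass turned sign as follows. The difference of the adenoma effect with FPKM, in the order of the limma settings above, was -0.072, -0.10 and -0.072 for Myc and -0.25, -0.27 and -0.25 for Apc. With 1 library left out it ranged from -0.051 to 0.22 for Apc and from -0.00289 to 1.60 for Lgr5, and Uty between adenoma types ranged from -0.12 to 0.14. Some lists turned direction in at least 1 fit with an adenoma left out, and no fit with a turned direction passed. For these lists the range of adjusted p over all fits with 1 adenoma left out, turned or not, is given next. It was 0.894 to 0.973 for macrophages in ApcMin/+ mice. In AOM/DSS mice it was 0.667 to 0.954 for tuft cells, 0.0498 to 0.392 for interferon genes and 0.0611 to 0.692 for B and plasma cells. Between adenoma types it was 0.0750 to 0.995 for WNT targets, 0.377 to 0.937 for stem cells, 0.00426 to 0.699 for colonocytes, 0.00162 to 0.971 for goblet cells, 0.715 to 0.976 for tuft cells, 0.0351 to 0.976 for proliferation, 0.406 to 0.879 for ribosome biogenesis, 0.361 to 0.897 for splice regulators, 0.0835 to 0.897 for inflammation and 0.801 to 0.992 for adipocytes. For the shared change it was 0.780 to 0.980 for endothelium. For the difference of the effects it was 0.0426 to 0.852 for goblet cells, 0.287 to 0.900 for ribosome biogenesis, 0.147 to 0.992 for mast cells, 0.0217 to 0.536 for enteric nerve and 0.155 to 0.986 for epithelium. A count of 0 allows 0.128 to 0.172 CPM, which limits folds of genes absent from 1 section.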

Other observations

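The tests of gene copies, and the test of colonocyte against epithelial genes, were chosen after the result was seen. Hoxd13, a posterior Hox gene, stood at 8.14 CPM in the ApcMin/+ section and 134 ± 62.0 CPM in its adenomas (SD, n = 3, log2 4.05 ± 0.68, SE, edgeR adjusted p = 0.0202), and at 196 CPM in the AOM/DSS section and 224 ± 50.0 CPM in its adenomas. Hoxd10 and Hoxd11 were also lower in the ApcMin/+ section (2.06 and 1.43 CPM) than in the AOM/DSS section (25.3 and 23.9 CPM). Hoxa13 and Hoxb13 were not, at 59.1 and 366 CPM in the ApcMin/+ section and 37.8 and 332 CPM in the AOM/DSS section. The sections are 1 library each, so whether the Hoxd13 rise reflects its adenomas or its section was not tested. Trpm5, a cation channel gene of tuft cells, fell by 2.73 in ApcMin/+ and by 3.07 in AOM/DSS adenomas on the log2 scale (adjusted p = 0.016 and 0.0284). Avil, another gene of the tuft list, went the other way. It stood at 6.53 CPM in the ApcMin/+ section and 153 ± 42.1 CPM in its adenomas, and at 15.5 and 136 ± 48.6 CPM in AOM/DSS mice. The tuft list did not pass in either model (camera adjusted p = 0.127 and 0.934). Mt4, a metallothionein gene, and Spp1, which encodes osteopontin, rose in ApcMin/+ adenomas by 7.81 ± 0.68 and 5.97 ± 0.96, and the chemokine gene Cxcl1 by 4.41 ± 0.83. The adipocyte gene Car3 went from 47.7 to 0.719 ± 0.355 CPM in ApcMin/+ mice and stood at 0.350 CPM in the AOM/DSS section.

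Between adenoma types, Cps1, the first enzyme of the urea cycle, stood at 23.7 ± 7.96 CPM in ApcMin/+ and 0.625 ± 0.660 CPM in AOM/DSS adenomas (SD, n = 3 each, edgeR adjusted p = 0.00909), with a log2 difference of -5.22, or -6.58 without AOM/DSS adenoma 1. The immunoproteasome gene Psmb8 was higher in AOM/DSS adenomas by 2.40 ± 0.41 (SE), as was the ubiquitin-like gene Ubd by 6.69 ± 1.04. Without AOM/DSS adenoma 2 these differences were 1.77 and 5.06 (adjusted p = 0.00534 and 0.00173). Psmb8 also differed between the sections, at 34.1 CPM (ApcMin/+) and 107 CPM (AOM/DSS). AOM/DSS adenomas 1 and 3, at 78.74 and 88.15 CPM, lay below their section. Of 4 Y-linked genes Kdm5d was higher in AOM/DSS adenomas (0.70 ± 0.11, adjusted p = 0.0126), and Ddx3y, Eif2s3y and Uty did not pass (0.37, 0.46 and 0.03, adjusted p = 0.0524, 0.135 and 0.902).

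The adenoma types differed in 3122 genes, and of the 10 splits of the 6 adenomas into 3 and 3 only 1, the real one, called as many, with 0 as the highest other. That is too few splits for a share under 0.05. Mice of different sex in the 2 models are argued against, since all 6 adenoma libraries held Y-linked counts (247 to 397 CPM). Of 9 genes called together with a copy, 5 had opposite calls, and reads assigned to a copy in 1 model may account for these: the summed CPM differed by a median of 0.078 on the log2 scale, though by -1.21 for Rps18, whose copy share shifted by 7.69 points between sections and 14.3 between adenomas, and by -0.33 for Rps2, and the definition was changed after a first look. The calls were not concentrated among copies and the classes left out with them, since 20.7% of tested genes were called without these and 18.1% with them. Near copies such as Hbb-bs and Defa3 stayed in, so reads shared between the remaining genes were not tested. ApcMin/+ mice were killed at 110 to 120 days, and AOM/DSS mice 70 days after AOM given at 6 to 7 weeks of age. These ages overlap, which argues against a large difference in age. Model, treatment and tissue around the adenoma stay open as untested differences. So does any difference in library preparation, sequencing or read processing between the models, which cannot be told apart from model here.

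The colonocyte, smooth muscle and enteric nerve lists had medians below 0 in both models, with 6, 8 and 2 genes of 23, 16 and 17 called lower in ApcMin/+ and 3, 12 and 3 in AOM/DSS adenomas, and 1 and 2 colonocyte genes called higher. The list calls were lost with an estimated correlation (adjusted p = 0.389 for each in ApcMin/+ mice, and adjusted p = 0.456, 0.244 and 0.456 in AOM/DSS mice, with an estimated correlation). Fewer epithelial cells in the adenoma samples met the bound written beforehand, since the epithelial medians were -0.60 and -0.58, under -0.5. The colonocyte medians lay a further -2.14 (ApcMin/+) and -2.44 (AOM/DSS) from the epithelial ones, more than the epithelial quartiles span (-0.87 to -0.25 and -0.85 to -0.15), which argues against it as the whole cause, in a test chosen afterwards. More muscle wall in the non-adenoma sections is consistent with the muscle and nerve medians, of which the highest of 4 was -2.33, and a loss of muscle within adenomas was not tested apart from it.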
